A study of Homo sapiens with 14 samples.

How the data were processed

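Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in DLD-1 cells, an established human colorectal adenocarcinoma line, with antibodies against STAT5 (C-17) and BCL6 (N-3). Per the labels' protocols, cells received an empty vector (control), a plasmid coding for a fragment of TIAM1 with vehicle (activator, meant to raise RAC1/PAK1 signalling) or the same plasmid with 20 microM EHT 1864, a RAC inhibitor, for 16 h (inhibitor), and chromatin was taken 20 h after transfection. The series holds 14 libraries in 6 groups: 2 control STAT5, 2 control BCL6, 2 activator STAT5, 3 activator BCL6, 2 inhibitor STAT5 and 3 inhibitor BCL6. Groups were taken from the titles, antibody and treatment labels. The labels do not say that replicates came from separate cultures, so the spread between them may be technical.

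Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie 0.12.7 were used and coordinates are of GRCh37; the role of each tool, the peak caller and its threshold are not given in the sources used here. The authors' deposited files are 6 lists of intervals with 1 whole-number value per interval and library. The header does not name the quantity, and it was read as a count of reads, in the control lists per interval: every value was 0 or at least 2, and in the first control BCL6 library the median width of intervals held by that library alone rose from 291 bp at a value of 2 to 316, 390, 468 and 533 bp at values of 3, 4, 5 and 6. In treated lists a value can belong to a peak wider than the interval listed: at RAD51B an activator STAT5 interval of 3 bp (68286992 to 68286994) and another of 186 bp (68287312 to 68287497) both have 5 and 8. The authors also deposited each interval's width in bp and its signed distance in bp from the start of an Ensembl gene, between 3000 bp upstream and 1000 bp downstream, with a gene symbol where the gene ID had one. Peak numbers in the control BCL6 list run up to 1176892 for 68393 intervals, and an interval near several gene starts is listed once per gene; each distinct interval was counted once here.

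Library columns were matched to samples by the condition and library number in their names and titles, and all 9 columns found a sample. The names of 2 lists carry a treated condition although their columns are of control libraries; every list is therefore described by the libraries it holds. The 4 separate lists hold control BCL6 (2 libraries), control STAT5 (2), activator STAT5 (2) and inhibitor BCL6 (3). The other 2 lists are the activator STAT5 intervals that overlap a control BCL6 peak and the inhibitor BCL6 intervals that overlap a control STAT5 peak: each of their 3593 and 391 intervals is found unchanged in the treated list. Control values in these shared lists can differ from those of the control peak overlapped. At BCL9 they are 5 and 0 in the shared list and 5 and 2 in the control BCL6 list. A control list takes an interval with a value in at least 1 library, whereas a treated list takes only intervals with a value of at least 2 in every library. The 5 activator BCL6 and inhibitor STAT5 libraries were not analysed here.

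The depth of each library is not given in the sources used here. The sum of its values over the intervals near gene starts is no depth, since neighbouring treated intervals can repeat the value of the same peak. That sum was 84510 and 97187 in control BCL6, 81105 and 100945 in control STAT5, 37629 and 44216 in activator STAT5, and 4390, 4606 and 5544 in inhibitor BCL6. Most values are the lowest possible (a value of 2 in 53.2% to 74.0% of nonzero entries per library), so a single interval carries little precision. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

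The planned tests and the 22 gene lists were fixed before the data were examined; tests added later are named as such. Overlap meant at least 1 shared bp and was compared with 100 random placements of the first list within its chromosomes, widths kept, as a one-sided permutation test; 0.0099 is the smallest p that 100 placements can give. Because the lists hold only intervals near gene starts, further placements were added after seeing the data: within the gene-start windows of the chromosome (the 44178 gene starts of the lists, 5.07% of the genome span), and at 1 of the 20 nearest other gene starts with the offset kept. Gene sets, gene lists and shares near gene starts were compared with 2-sided Fisher's exact tests and Benjamini-Hochberg adjustment. The planned background was all 59778 symbols of the reference table, which is of another assembly (GRCh38.p14) and was used for names and gene types only; 26166 of the 26333 symbols in the lists matched, directly or through an older symbol (24805 directly). Its 20056 protein-coding symbols were a further background set in advance, as were random lists matched on gene length. Density along the genome was counted in 5 Mb autosomal bins with at least 20 gene starts, and log density was regressed on log control density with a quasi-Poisson model and 95% interval.

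Gene lists covered known STAT5 and BCL6 targets, damage signalling, homologous recombination with the Fanconi pathway, end joining, nucleotide excision, base excision and mismatch repair, the RAC1/PAK and JAK-STAT pathways, cell cycle, apoptosis, the WNT pathway, colon epithelium, B cells, fibroblasts with endothelium, long neuronal adhesion genes, fragile-site genes, and the olfactory receptor, zinc finger, ribosomal protein and histone families. Genes are named by a fixed rule: target-list genes in a list (at most 10 in full), the 5 intervals per list with the highest mean value, up to 4 members per enriched list and per repair list by best value, and the 10 genes with the best summed rank held by both the STAT5 list of 1 treated condition and the BCL6 list of the other. Other genes are said to be chosen after their values were seen. Some genes that this rule selects are counted in the tests but not reported by name here. The per-interval values are the authors' and were used to describe, rank and filter intervals within a list.

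Differential binding between treated and control libraries was planned but not run, since no list holds both groups of a planned contrast. Motif shares, an own assignment to gene starts, a stricter p threshold and a test of values between lists were not run either: no genome of this build was used here, the lists have no p column, and no normalization is shared across lists. Placement, gene list and slope code was tested on simulated data. With no planted overlap the mean fold was 0.998 and 1 of 10 simulated lists passed 0.05; with 600 overlaps planted among 14047 intervals, 574.8 were recovered. A WNT list planted at 60% was called in 10 of 10 simulations against 1 of 350 other lists, and simulated slopes of 1 and 2 came back as 1.01 and 1.99. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Alternatives varied the overlap rule, the intervals and chromosomes used, the placement, the background and the control libraries.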

Results

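The lists analysed here describe where STAT5 and BCL6 ChIP-seq intervals lay near gene starts in DLD-1 colorectal cells with an empty vector, with the RAC1/PAK1 activator plasmid or with that plasmid and the inhibitor. Both proteins are transcription factors that recognise similar DNA sequences; STAT5 is known mainly as an activator and BCL6 as a repressor. The control BCL6 list held 68393 intervals with a median width of 305 bp and the control STAT5 list 68320 with a median of 304 bp. The activator STAT5 list held 14047 intervals (median 142 bp) and the inhibitor BCL6 list 1652 (median 85 bp). These numbers do not compare occupancy between conditions, because a control interval needed a value in at least 1 of its 2 libraries and a treated interval a value of at least 2 in every library. Only 6287 control BCL6 intervals (9.19%) and 6381 control STAT5 intervals (9.34%) had a value in both libraries. Moving 1 library's intervals to neighbouring gene starts (20 placements) gave 5955 ± 74.2 (BCL6) and 5847 ± 70.85 (STAT5) overlaps with the other. Replicates shared 1.06 and 1.09 times as many intervals as placement gave, and placement was confined to gene starts that hold an interval in the lists. Control libraries of different antibodies stood 1.11 to 1.13 times above it. Those pairs compare separate lists, whereas replicates share 1 merged list, so the ratios do not measure antibody specificity. Across intervals, which are not independent replicates, the values of replicate libraries had a Spearman's rho of 0.0161 in control BCL6 and 0.0165 in control STAT5. It was 0.0296 in activator STAT5 and 0.0215 to 0.0795 in inhibitor BCL6; every value in these treated lists is 2 or more. Pearson's r on the same intervals was 0.562 in activator STAT5 and 0.355 to 0.664 in inhibitor BCL6. Among control intervals with a value in both libraries it was 0.0267 (BCL6) and 0.0311 (STAT5). On the log2 scale the treated r fell to 0.112 and to 0.234 to 0.269. The highest values can also repeat, as 48 and 182 do at neighbouring activator STAT5 intervals on chromosome 10, so r on the linear scale is no measure of agreement across the list.

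The first comparison asked which sites with BCL6 in control cells carried STAT5 after RAC1/PAK1 activation, the switch that the series title names. Activator STAT5 intervals lay on control BCL6 peaks at ID1, a known STAT5 target that codes for an inhibitor of differentiation, and at the DNA repair genes FANCL, BLM, RAD51B, XRCC1, LIG3, TDG and FEN1. At 9 of the 40 gene list members in this shared list, the large families left aside, every shared interval began or ended directly beside a control STAT5 peak: CDK1, ID1, LIMK2, RAD23B, RAD51B, RAD54B, SOCS5, WASF1 and XRCC1. In total 3593 of the 14047 activator STAT5 intervals (25.6%) overlapped a control BCL6 peak. Intervals placed at random on their chromosomes gave 166 ± 13.2 (SD over 100 placements), a ratio of 21.6 ± 1.72 (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Both lists hold only intervals near gene starts, and most of that ratio was also given by placement at other gene starts. Intervals moved to 1 of the 20 nearest other gene starts overlapped 2980 ± 48.5 times, 82.9% of the observed number. The observed overlap stood 1.21 ± 0.02 times above that mean and above all 100 placements, which ranged from 2818 to 3087 (one-sided permutation p = 0.0099). Placement that also kept off control STAT5 peaks, which no activator STAT5 interval overlapped, gave a ratio of 1.24 ± 0.02. Only the 44178 gene starts with an interval in at least 1 of the 4 separate lists were open to placement. Of these, 37925 had a control BCL6 interval. Starts without any interval were left out, so the placed share can be too high and these ratios too low. As a measured background from cells with the empty vector, control STAT5 peaks overlapped control BCL6 peaks in 20610 of 68320 cases (30.2%), 1.10 times the neighbouring placement. Control STAT5 peaks with a value in both libraries, trimmed to 142 bp like the activator list, stood 1.27 ± 0.03 times above it.

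**Figure D1:**
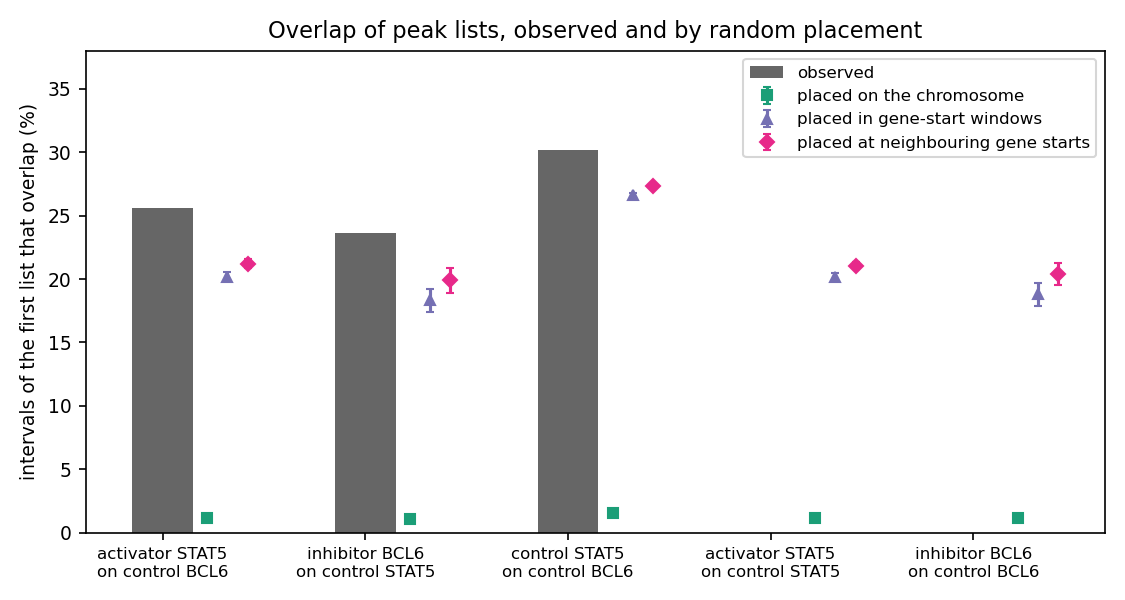
Share of the intervals of a first list that overlap a second list, in percent (y axis), for 5 pairs of lists (x axis). Grey bars are observed shares, and squares, triangles and diamonds are means of 100 placements on the chromosome, in gene-start windows and at neighbouring gene starts, with SD as error bars; 25.6% of activator STAT5 intervals lay on control BCL6 peaks, and 0 intervals overlapped the control list of their own antibody.

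Among the genes of the shared list, FANCL, the ubiquitin ligase of the Fanconi pathway, had an interval at chromosome 2, 58470659 to 58470850 with values of 2 and 2 in the activator STAT5 libraries and 3 and 6 in the control BCL6 libraries. PPM1D, a phosphatase that dampens damage signalling, had values of 4 and 2 in activator STAT5 and 3 and 6 in control BCL6 at chromosome 17, 58675718 to 58676034. H2AX, the histone phosphorylated at DNA breaks, had 2 and 7 beside 3 and 0 at chromosome 11, 118967161 to 118967461. RAD51B, a recombination gene, had values of 5 and 8 beside 2 and 0 at chromosome 14, 68287312 to 68287497. BLM, a helicase, had 5 and 2 beside 2 and 2 at chromosome 15, 91260064 to 91260321. XRCC1, a scaffold of base excision repair, had 2 and 6 beside 0 and 2 at chromosome 19, 44080795 to 44080886. LIG3, its partner ligase, had 4 and 2 beside 2 and 0 at chromosome 17, 33306922 to 33307181. The ID1 interval at chromosome 20, 30190265 to 30190345, lay at -2822 bp from the gene start, with 2 and 4 in activator STAT5 and 0 and 4 in control BCL6. EPCAM, CEACAM5 and CDH1, all surface proteins of colon epithelium, were also in the shared list. FANCL and EPCAM lie on chromosome 2 between 30 and 75 Mb, where every list was dense.

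By group, the shared list held 6 of 23 base excision repair genes (FEN1, LIG3, NEIL3, TDG, TDP1 and XRCC1). It also held 4 of 36 damage signalling genes (H2AX, MDC1, PPM1D and RAD17) and 4 of 31 homologous recombination and Fanconi genes (BLM, FANCL, RAD51B and RAD54B). Of the remaining repair lists it held 2 of 23 nucleotide excision repair genes (ERCC8 and RAD23B), 1 of 8 mismatch repair genes and 0 of 10 end joining genes. Against all symbols of the reference, base excision repair was over-represented (26.1% against 3.62% of other genes, Fisher's exact test, two-sided, adjusted p = 0.000496). All members of the 22 lists are protein-coding, and most of those symbols are not, so that background favours every list. Against protein-coding genes alone, of which 7.41% outside the list were in the shared list, Fisher's exact test gave an odds ratio of 4.41, p = 0.00561 and an adjusted p of 0.185, which did not pass 0.05. The WNT pathway (6 of 48, among them APC, BCL9, GSK3A and DKK1) and the cell cycle (5 of 43, among them CDK1, E2F5 and TFDP1) passed Fisher's exact test against all symbols, with adjusted p of 0.0173 and 0.0418. Olfactory receptors (29 of 390, 0.00108) and zinc fingers (41 of 665, 0.00332) passed too. None of these 5 lists passed against protein-coding genes by Fisher's exact test, where 1 of the 22 lists, base excision repair, had an unadjusted p under 0.05. CDH1, the remaining named member of the cell cycle list, is the symbol of the adhesion protein E-cadherin. It was counted among the 5 of 43 cell cycle genes, and the test was not repeated without it. In the other lists the shared list held 3 of 20 colon epithelium genes and 3 of 35 JAK-STAT genes (IL6ST, PIAS4 and SOCS5). It held 3 of 35 apoptosis genes (BCL2A1, BIRC2 and BIRC3), 2 of 41 RAC1/PAK genes (LIMK2 and WASF1) and 1 of 12 B cell markers (CR2).

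The whole activator STAT5 list, which was free of any base of the control STAT5 list, held DNA repair genes in the same families. It contained 13 of 31 homologous recombination and Fanconi genes, with the highest values at RAD51B (5 and 8), FANCL (3 and 5), BLM (5 and 2) and FANCC (2 and 5). It also contained 11 of 23 base excision repair genes, led by XRCC1, APTX, LIG3 and TDG. Of 36 damage signalling genes it held 12, where H2AX, RAD50 and RPA1 each had values of 2 and 7 and RAD17 had 3 and 6. It held 9 of 23 nucleotide excision repair genes, led by GTF2H3 (2 and 8) with CCNH, CDK7 and ERCC1. It held 2 of 8 mismatch repair genes, and of the 10 end joining genes XRCC5 (2 and 5), which codes for KU80. Of the WNT pathway 21 of 48 genes were present, led by ZNRF3, a receptor-removing ubiquitin ligase (5 and 5), FZD5 (3 and 6), FZD4 (5 and 3) and WNT1 (2 and 6). Of the cell cycle list 16 of 43 were present, with CDK2, CCNB2, E2F5 and RBL1 leading. Of colon epithelium it held 8 of 20, with EPCAM (4 and 18), CDH17 (2 and 13), HNF4A (4 and 9) and TFF3 (3 and 5). Among these leading intervals, at least those at XRCC1 and APTX directly touched a control STAT5 peak. At APTX the interval ended at 33024247 and the peak began at 33024248. The intervals at RAD51B (3 bp) and RPA1 (18 bp) were narrow. Contact was not counted by gene over the whole list, so these genes are not shown to have gained STAT5.

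The background of all symbols favours every gene list, since all their members are protein-coding and most symbols are not. Against all symbols, of which 12.6% to 12.8% outside each list were in the activator STAT5 list, 10 of the 22 gene lists were over-represented by Fisher's exact test. By that exact test, members were present at 47.8% in base excision repair (adjusted p = 0.000183), 43.8% in the WNT pathway (7.1e-07) and 41.9% in homologous recombination (0.000203). Colon epithelium passed with an adjusted p of 0.00556 by the exact test. The shares were 39.1% in nucleotide excision repair (0.00377), 37.2% in cell cycle (0.000178) and 33.3% in damage signalling (0.00339). Ribosomal proteins (30.7%, 3.89e-05), olfactory receptors (29.0%, 3.99e-16) and zinc fingers (23.3%, 9.05e-13) passed as well. Against protein-coding genes alone, of which a median of 26.1% outside the lists were in it, 0 of the 22 passed by Fisher's exact test with Benjamini-Hochberg adjustment. There 2 lists had an unadjusted exact p under 0.05, the WNT pathway (odds ratio 2.21, p = 0.0079, adjusted p = 0.195) and base excision repair (odds ratio 2.60, p = 0.029, adjusted p = 0.348). Homologous recombination had an odds ratio of 2.05 (adjusted p = 0.486 by the same exact test). The other lists had 2 of 18 STAT5 targets, 6 of 24 BCL6 targets, 8 of 41 RAC1/PAK genes, 6 of 35 JAK-STAT genes and 8 of 35 apoptosis genes. They also had 4 of 12 B cell markers, 3 of 14 fibroblast and endothelial markers, 4 of 20 neuronal adhesion genes, 4 of 20 fragile-site genes and 15 of 66 histones. The end joining and mismatch repair lists and these 10 passed against neither background.

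**Figure D2:**
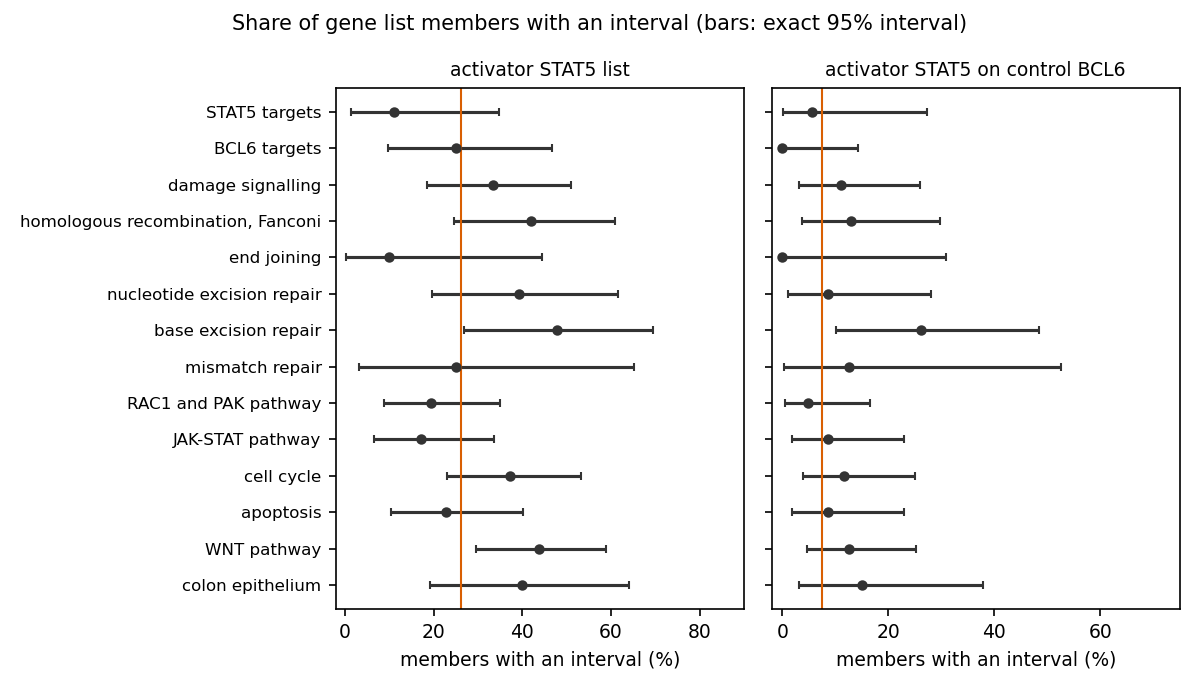
Percent of the members of 14 gene lists (y axis) with an interval in the activator STAT5 list and in its part on control BCL6 peaks (x axis in percent, 2 panels). Points are shares with exact 95% intervals and the vertical line is the median, over these lists, of the share among other protein-coding genes (26.1% and 7.43%); the highest point of both panels is base excision repair, at 47.8% and 26.1%.

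Among known targets, STAT5 intervals after activation lay at BCL6 itself, the repressor's own gene, and at ID1, CDKN1B, ATR and ID2. At BCL6 the interval at chromosome 3, 187463723 to 187464050, lay at -208 bp from the gene start with values of 5 and 5. The 2 control BCL6 peaks at this gene start did not overlap it, and the control STAT5 list had none there. CDKN1B, which codes for the cell cycle inhibitor p27, had values of 2 and 2 at chromosome 12, 12868198 to 12868328. ATR, the replication stress kinase, had 3 and 2 at chromosome 3, 142298721 to 142298784, and ID2, a relative of ID1, had 2 and 3 at chromosome 2, 8816858 to 8817053. Of 18 STAT5 targets, 17 were in the control BCL6 list, 13 in the control STAT5 list and 2 in the activator STAT5 list. Of 24 BCL6 targets, 17 were in the control BCL6 list, 18 in the control STAT5 list, 6 in the activator STAT5 list and 2 in the inhibitor BCL6 list. CISH, SOCS2 and MYC, classical STAT5 targets, and PRDM1 and CDKN1A, classical BCL6 targets, had no interval in a treated list. These 5 were chosen after their values were seen. The first 3 had control STAT5 peaks and the other 2 control BCL6 peaks. Treated lists shared no base with control peaks of their own antibody and had a stricter rule for entry. The numbers of targets per list therefore do not measure a loss of binding.

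The second comparison asked which sites with STAT5 in control cells carried BCL6 when RAC1/PAK1 was inhibited. Inhibitor BCL6 intervals lay on control STAT5 peaks at FANCL, at RHOG, a RAC-related GTPase, at CDKN2C, the cell cycle inhibitor p18, and at the long adhesion genes CTNNA3 and CSMD3. At FANCL the interval at chromosome 2, 58468390 to 58468454, at 117 bp from the gene start, had values of 3, 3 and 6 in the inhibitor BCL6 libraries and 0 and 2 in the control STAT5 libraries. In total 391 of 1652 inhibitor BCL6 intervals (23.7%) overlapped a control STAT5 peak, 21.7 ± 5.01 times the mean of placements on the chromosome (one-sided permutation p = 0.0099). Placement at neighbouring gene starts gave 329 ± 16.3, 84.1% of the observed number, and the observed overlap stood 1.19 ± 0.06 times above it and above all 100 placements (293 to 366, one-sided permutation p = 0.0099). Here too only gene starts of the lists were open to placement. Kept off control BCL6 peaks, placement gave 1.24 ± 0.05, and control BCL6 peaks with a value in both libraries, trimmed to 85 bp, stood 1.25 ± 0.03 times above neighbouring placement on control STAT5 peaks. That excess no longer passed among inhibitor intervals with a value of at least 3 in every library (1.26 ± 0.21, one-sided permutation p = 0.089).

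The inhibitor BCL6 list as a whole held CD44, a surface receptor among the BCL6 targets (2, 3 and 2 at chromosome 11, 35161352 to 35161490). Of the repair lists it held 1 of 36 damage signalling genes, FANCL and SLX4 among 31 homologous recombination and Fanconi genes, TDG among 23 base excision repair genes, and 0 of the nucleotide excision, mismatch repair and end joining lists. JAK1, JAK2 and LIFR of 35 JAK-STAT genes and CCNE1, CDKN2C, E2F5 and TFDP2 of 43 cell cycle genes were present. Against all symbols, Fisher's exact test passed for JAK-STAT (8.57% against 1.60%, adjusted p = 0.0402) and the cell cycle (9.30% against 1.59%, adjusted p = 0.0117). So did olfactory receptors (14 of 390, adjusted p = 0.0147) and zinc fingers (21 of 665, adjusted p = 0.0107) by the exact test. Against protein-coding genes 0 of 22 lists passed, and 0 had an unadjusted p under 0.05, with an adjusted p of 0.696 for JAK-STAT and 0.486 for the cell cycle. In the shared list, the 2 of 20 neuronal adhesion genes CTNNA3 and CSMD3 passed Fisher's exact test against all symbols (adjusted p = 0.00809) and not against protein-coding genes (p = 0.0127, adjusted p = 0.209).

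Within an antibody, treated and control lists shared no base. Neither FANCL, EPCAM nor any other gene had an activator STAT5 interval that shared a base with a control STAT5 peak: 0 of 14047 overlapped, where placement gave 167 ± 12.6 on the chromosome and 2959 ± 43.8 at neighbouring gene starts. Likewise 0 of 1652 inhibitor BCL6 intervals overlapped a control BCL6 peak, where placement gave 18.7 ± 4.69 and 337 ± 14.0. No p is given for these counts, which base-by-base removal of control peaks in the making of the lists would fix at 0. With centres within 1000 bp counted as shared, the numbers were 15.7 ± 0.678 (STAT5) and 16.2 ± 2.31 (BCL6) times those of placement on the chromosome. At ID1 the activator interval ended at 30190345 and a control STAT5 peak began at 30190346. Such direct contact was found for 2651 activator STAT5 intervals (18.9%, 95% interval 18.2 to 19.5) with control STAT5 peaks and for 9 with control BCL6 peaks. For inhibitor BCL6 intervals it was 236 (14.3%, 12.6 to 16.1) with control BCL6 peaks and 1 with a control STAT5 peak. Touching intervals were narrower, with medians of 89 bp against 157 bp for other activator intervals and 64 bp against 89 bp for other inhibitor intervals. In the shared lists 716 of 3593 and 57 of 391 intervals touched a control peak of the same antibody.

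**Figure D3:**
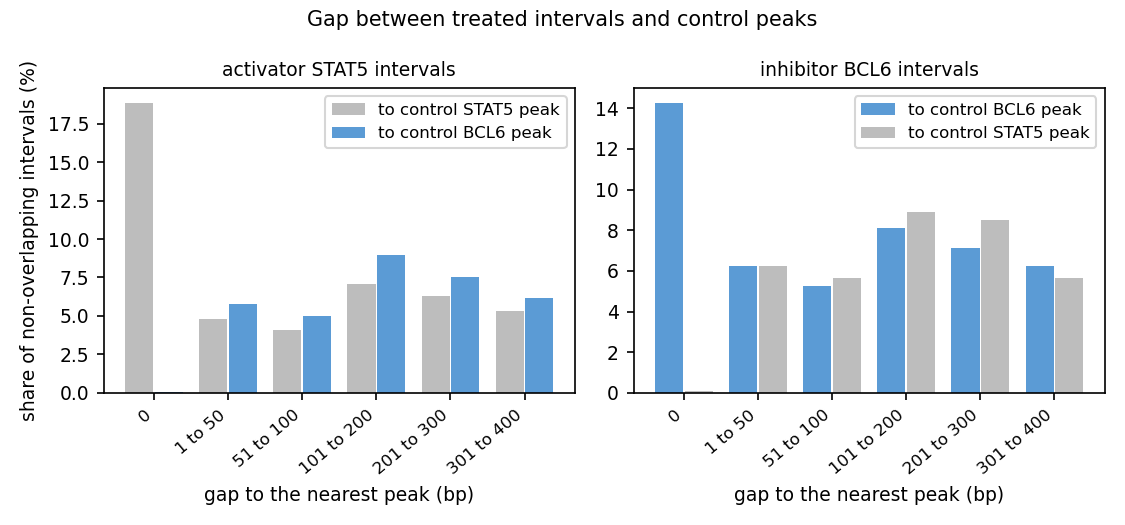
Share of treated intervals in percent (y axis) by the gap in bp to the nearest control peak (x axis), for activator STAT5 (left) and inhibitor BCL6 intervals (right) that do not overlap the control list in question. Bars give the control list by colour, and a gap of 0 bp is direct contact, which 18.9% of activator STAT5 intervals had with a control STAT5 peak.

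At the level of genes, BCL6, ID2 and most other genes with an activator STAT5 interval also had a control BCL6 peak somewhere in the same window. Among protein-coding genes, 4569 of the 5231 genes with an activator STAT5 interval (87.3%) had a control BCL6 peak, against 69.1% of other genes (Fisher's exact test, two-sided, odds ratio 3.08, adjusted p = 6.32e-162). For control STAT5 peaks, which no activator interval overlapped, the number was 4615 genes (88.2%, Fisher's exact test, odds ratio 3.18, adjusted p = 3.5e-163). Of the 661 genes with an inhibitor BCL6 interval, 606 had a control STAT5 peak (91.7%, exact test, odds ratio 3.80, adjusted p = 5.74e-29). A control BCL6 peak was found at 569 (86.1%, exact test, odds ratio 2.23, adjusted p = 1.99e-14). The activator STAT5 and inhibitor BCL6 lists shared 254 genes (exact test, odds ratio 1.81, adjusted p = 1.52e-12). Genes are not independent replicates, and the difference between the odds ratios was not tested. Of the 20056 protein-coding symbols, only 17196 were in at least 1 of the 4 lists. The rest count as genes without any peak, also where a gene ID near a peak carried no symbol, which raises these odds ratios. The overlap of gene sets was not tested against listed genes alone.

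In control cells most members of every repair list had a STAT5 peak and most had a BCL6 peak; the control lists were not tested against each other by gene group. All 8 mismatch repair genes, among them MLH3 and EXO1, were in both lists. Of damage signalling genes 32 of 36 had a control BCL6 peak (ATM, H2AX, PPM1D and RAD50 had the highest values) and 33 a control STAT5 peak (TOPBP1, PPM1D, MDC1 and WEE1). Homologous recombination had 25 and 29 of 31, base excision repair 21 and 21 of 23, nucleotide excision repair 17 and 18 of 23, and end joining 8 and 7 of 10. Colon epithelium had 20 and 18 of 20, fibroblast and endothelial markers 12 and 11 of 14, and B cell markers 10 and 10 of 12. Fisher's exact test passed for 21 (BCL6) and 20 (STAT5) of 22 lists against all symbols, of which 37.4% and 37.8% had a peak. Against protein-coding genes, of which 73.9% and 74.9% had a peak, it passed for 1 of 22 in either list. That list was the histone genes, which were under-represented (27 and 28 of 66, odds ratios of 0.243 and 0.245, adjusted p = 1.61e-06 in both by the exact test). Of the gene IDs of 300 to 600 bp in the histone cluster of chromosome 6 between 26 and 28 Mb, 35 of 47 carried no symbol in the lists (74.5%, against 40.4% of all gene IDs).

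The share of intervals close to gene starts was compared in 4 pairs of lists, and none passed Fisher's exact test. Interval starts lay within 500 bp of a gene start in 23.6% of interval and gene pairs for control BCL6 (95% interval 23.3 to 23.9), and 23.9% for control STAT5. The share was 23.7% for activator STAT5 and 22.4% for inhibitor BCL6 (20.5 to 24.4). In the shared lists, which were not tested, it was 22.1% (20.8 to 23.4) for activation and 21.9% for inhibition. The 4 two-sided tests between lists gave adjusted p from 0.323 to 0.482. Each class of 500 bp held between 10.7% and 14.0% of pairs in the 4 lists, beside 12.5% if evenly spread, and the class just downstream of gene starts held 11.4% in control BCL6 (11.1 to 11.6). The intervals near gene starts were 5.81% (control BCL6), 6.01% (control STAT5), 6.19% (activator STAT5) and 5.73% (inhibitor BCL6) of the highest peak number in their lists. Windows of the 44178 gene starts found in the lists cover 5.07% of the genome span. Gene starts without an interval are not in these windows, so the shares show no excess near gene starts.

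Along the genome, a stretch of the short arm of chromosome 2 that holds EPCAM, FANCL, PIGF and OTX1 was dense in every list. Between 30 and 75 Mb, a range chosen after the values were seen, control BCL6 peaks were 1.68 times (95% interval 1.61 to 1.76) and control STAT5 peaks 1.52 times (1.44 to 1.59) as frequent per gene start as in other autosomal bins. Activator STAT5 intervals were 2.60 times (2.40 to 2.82) and inhibitor BCL6 intervals 5.66 times (4.76 to 6.69) as frequent. In the shared lists the ratio was 4.43 (3.89 to 5.01) for activator STAT5 on control BCL6 and 8.02 (5.84 to 10.8) for inhibitor BCL6 on control STAT5. Each control library showed it alone, at 1.93 and 1.75 for BCL6 and 1.73 and 1.57 for STAT5. Chromosome 2 was not the only such place. The bin at chromosome 11, 5 to 10 Mb, also chosen after its values were seen, had relative densities of 1.39 (control BCL6) and 1.37 (control STAT5). There they were 2.11 in activator STAT5 and 2.55 in inhibitor BCL6. The 95% intervals of the density ratios count each interval as independent and cover counting error only. Neighbouring treated intervals can belong to 1 peak, so those limits can be too narrow.

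**Figure D4:**
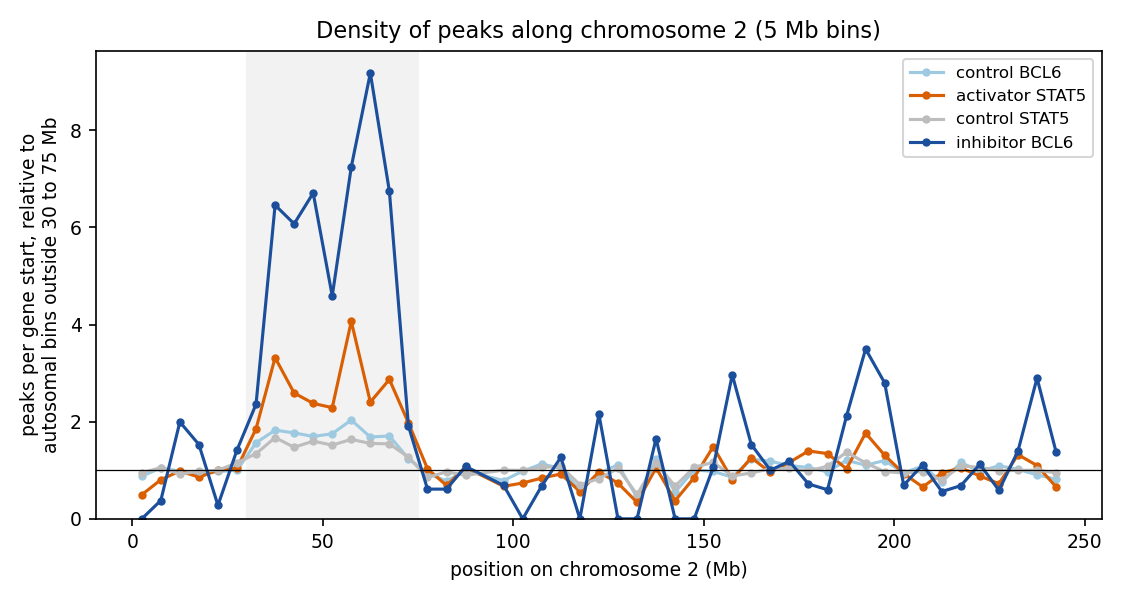
Peaks per gene start in 5 Mb bins along chromosome 2 (x axis in Mb), relative to autosomal bins outside the shaded range of 30 to 75 Mb (y axis, ratio, with a line at 1), for the 4 separate lists (coloured lines). In the shaded range the ratio over all 9 bins was 1.52 to 1.68 in the control lists, 2.60 in activator STAT5 and 5.66 in inhibitor BCL6.

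The treated intervals with the highest values lay mostly at gene IDs without a symbol. In the activator STAT5 list the first was at chromosome 21, 9826848 to 9826855, with values of 100 and 131. The next 4 were at chromosome 10 between 42391972 and 42393946, with values from 30 to 182. The inhibitor BCL6 list began at chromosome 10, 42398438 to 42398448, with values of 8, 66 and 83, followed by RNU2-42P, a small nuclear RNA pseudogene (14, 17 and 51). The control BCL6 list began with NBPF1, of a segmentally duplicated gene family (3 and 22), and PDE4DIP, a centrosome protein gene, was also among its first 5 (15 and 2). The control STAT5 list began at a gene ID without a symbol at chromosome 4, 49512841 to 49513620 (3 and 13), and HIST1H2BD, a histone gene, was among its first 5 (10 and 5). Of the top 20 intervals, 4 of the activator STAT5 and 7 of the inhibitor BCL6 list had a symbol, and 12 in each of the control BCL6 and control STAT5 lists.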

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

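The placements at gene starts, the thresholds of 3 or more and of a value in every library, the settings without chromosome 2 from 30 to 75 Mb or without touching intervals, the background of listed protein-coding genes and the left-out control libraries were chosen only after the data were seen. Of 50 overlaps between antibodies under other settings, 49 kept their direction and side of 0.05. So did all 36 of the gene set overlaps, none of them against listed genes alone, and the 4 slopes. Many of the 50 used placement on the whole chromosome, where lists confined to gene starts overlap far above placement in any case. Those settings could hardly have differed. For activator STAT5 with inhibitor BCL6, the setting of control peaks with a value in both libraries changed neither list. At neighbouring gene starts, inhibitor BCL6 intervals with a value of at least 3 in every library stood 1.26 times above placement on control STAT5 peaks, with a one-sided permutation p = 0.089; only 100 such intervals were left. With centres within 1000 bp counted as shared, the lack of overlap within an antibody turned to ratios of 15.7 (STAT5) and 16.2 (BCL6), since that rule also takes in neighbours that share no base. A reciprocal overlap of 50 percent left 0 shared inhibitor and control BCL6 intervals, where placement also gave few.

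List sizes changed with the rule for entry, which does not account for all of their differences. A value of 3 or more in every library left 667 control BCL6, 644 control STAT5, 2376 activator STAT5 and 100 inhibitor BCL6 intervals. It left 8 and 1 in the shared lists. A value in every library left 6287, 6381, 320 and 41 in the control and shared lists. Counts of the shared lists, and their gene numbers below, use the control values deposited in those lists. By the values of the control peaks themselves, 539 activator STAT5 and 75 inhibitor BCL6 intervals overlapped a control peak with a value in both libraries. Leaving out a control library gave 34975 to 39705 (control BCL6), 33713 to 40988 (control STAT5), 1828 to 2085 and 200 to 232 (shared) intervals. Counted on the control peaks that were left, 1938 to 2216 activator STAT5 and 223 to 245 inhibitor BCL6 intervals overlapped a peak of the other antibody. Gene numbers in the upper 50 percent of each list by value were 4156, 480, 1110 and 121 for activator STAT5, inhibitor BCL6 and the shared lists. A value in every library left 3774, 4041, 208 and 31 genes in the control and shared lists, and a left-out control library 1108 to 1323 and 130 to 153 in the shared lists. Treated lists cannot be rebuilt without a library, since they hold only intervals with a value in every library.

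Gene list calls depended on the background. All members of the 22 lists are protein-coding, and protein-coding genes were in each of the 6 peak lists more often than all symbols were. Calls against all symbols alone therefore do not single out a gene group. Against protein-coding genes, with or without the chromosome 2 range, 1 of 22 lists passed in each control list and 0 in the 4 others. With listed genes, intervals in every library or length-matched lists it was 0 in all 6. The length-matched lists also used listed genes alone, which hold 32 of the 66 histone genes. They therefore do not single out an effect of gene length. With the highest values only, 1 list passed in inhibitor BCL6 and 0 in the activation shared list. Densities on chromosome 2 ranged from 1.75 to 1.93 and from 1.57 to 1.73 over single control libraries. Correlations of values between replicates fell on the log2 scale to 0.112 in activator STAT5 and 0.234, 0.257 and 0.269 in inhibitor BCL6, from 0.562 and 0.355 to 0.664 on the linear scale. The cause of these shifts was not tested beyond the construction named.

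No paired analysis was possible because no list holds both groups of a planned contrast and the overlap tests have no replicates. Not run were motif shares and their windows and backgrounds, an own gene start assignment, a p threshold 10 times stricter, values between lists, and DESeq2 size factors, filters and left-out libraries for differential binding. The low values, mostly 2, limit what single intervals show.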

Other observations

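The tests of touching intervals, of width-matched control peaks and of the part of the overlap above neighbouring placement, and the choice of the chromosome 2 range, were made only after the results were seen, as were the placement off control peaks of the same antibody, the exclusion of an interval's own gene start from neighbouring placement and the rule of 1 SD around the bound of 1.2; counts per chromosome had been seen before the regional slopes were tested.

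Genes shared by the activator STAT5 and inhibitor BCL6 lists, which come from cells with the same plasmid, numbered 359. The 10 with the best summed rank were DUX4L50, RNA5-8SP2, FANK1, NBPF1, PDE4DIP, PIGF, OTX1, ZNF195, GAPDHP25 and RN7SL604P. PIGF, an enzyme gene of membrane anchor synthesis, OTX1, a homeobox gene, GAPDHP25 and RN7SL604P lie on chromosome 2 between 30 and 75 Mb, and NBPF1, PDE4DIP, DUX4L50 and RNA5-8SP2 belong to duplicated or repeated families. At FANK1 the activator interval (15 and 8, chromosome 10, 127583095 to 127583211) and the inhibitor interval (4, 10 and 4, 127583304 to 127583335) lay next to each other, and at OTX1 values were 5 and 10 beside 2, 4 and 6. Activator STAT5 and inhibitor BCL6 intervals themselves overlapped 73 times, 1.70 ± 0.24 times neighbouring placement (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Of the top 20 activator STAT5 intervals, 13 lay within 20000 bp of a top inhibitor BCL6 interval, 10 within that distance of a top control BCL6 interval and 0 of a top control STAT5 interval. Of the top 20 inhibitor BCL6 intervals, 7 lay near a top activator STAT5, 8 near a top control BCL6 and 1 near a top control STAT5 interval, and 0 of the top control STAT5 intervals lay near a top control BCL6 interval; several of these intervals share a locus, so the numbers are not of separate places.

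Activator STAT5 intervals at ID1, BLM and XRCC1 lay on control BCL6 peaks, although those at ID1 and XRCC1 and 1 at BLM also touched a control STAT5 peak. Inhibitor BCL6 intervals at FANCL and RHOG lay on control STAT5 peaks. The overlaps of the whole lists stood 1.21 ± 0.02 and 1.19 ± 0.06 times above placement at neighbouring gene starts. The bound of 1.2, set before this test was run but after the lists had been seen, lies within 1 SD of both; before the own gene start was excluded both ratios lay below it. Placement that also kept off control peaks of the same antibody, as the treated lists do, gave 1.24 ± 0.02 and 1.24 ± 0.05. The first lies above the bound by more than its SD and argues against placement as the whole explanation on activation, whereas on inhibition the bound does not decide. Leaving gene starts without any listed interval out of the placement can lower all these ratios. The observed 3593 and 391 overlaps lay 613 and 62.1 above the mean of neighbouring placement and above all 100 placements, which argues against placement for that part in both; this reads the overlap test of the report again and is no further evidence. Read accumulation common to all libraries, whatever the antibody or treatment, may account for that part: control STAT5 peaks with a value in both libraries stood 1.18 times above placement on control BCL6 peaks, and width-matched control peaks 1.27 and 1.25 times. These ratios cannot tell read accumulation from binding of both factors at the same places, since the factors recognise similar sequences and motif shares were not run. An exchange of BCL6 for STAT5 on treatment, which the design names, stays open and was not tested, since activator BCL6 and inhibitor STAT5 libraries were not analysed here.

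Regional density, with EPCAM and FANCL in its densest stretch, rose more steeply in treated lists than in control lists. More DNA copies per cell in some regions, with reads falling at random, may explain it: a list that needs several reads in every library then rises faster than a list that needs them in 1. The slopes of log density on log control density had 95% intervals above 1, with lower estimates of 1.4 for activator STAT5 and 2.41 for inhibitor BCL6, and stayed above 1 without chromosome 2 from 30 to 75 Mb (1.21 and 1.60). DLD-1 cells are known to carry extra material from the short arm of chromosome 2, as background to this hypothesis. Mapping, accessibility and a response to treatment were not tested.

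Direct contact with control peaks of the same antibody, as at ID1, was found for 236 inhibitor BCL6 intervals, against 1 in contact with a control peak of the other antibody, and for 2651 activator STAT5 intervals against 9. The lower ratio, 236, rests on that 1 contact and is not precise. Intervals left over when control bases were taken away from wider intervals could give this, together with the 0 overlaps within an antibody and the narrower touching intervals. Such remnants would lie beside control binding of the same factor and would not be sites gained on treatment. Touching intervals were 716 of 3593 and 57 of 391 in the shared lists; contact alone does not show that each is a remnant, and no biological explanation was tested.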
